A study of Mus musculus with 6 samples.

How the data were processed

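The samples were 6 RNA-seq libraries of the mouse trophoblast stem (TS) cell line F4, of which 3 came from cells grown for 2 days with 20 µM diethylstilbestrol (DES) and 3 from cells grown with its vehicle, ethanol. Per the labels' protocols, the cells grew in medium with FGF4 and heparin, most of it conditioned by mitotically inactive embryonic fibroblasts. Total RNA was extracted with TRIzol and PureLink columns, and single-end libraries were made with a stranded TruSeq kit after depletion of ribosomal RNA with Ribo-Zero Gold. Groups and replicate numbers were taken from the sample titles.

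The values used were whole-number read counts per gene symbol, deposited by the authors with 1 table per library and no normalization. The submitters' processing notes name STAR 2.3.1z12, HTSeq 0.6.1 and the mouse genome build mm9, without saying which settings were used. The gene annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap on opposite strands, and members of families with near-identical copies, may therefore share or lose reads, and their counts are uncertain; this concerns the Serpinb9, Prl, cathepsin, Rhox, keratin and ribosomal protein genes named in the results. Counts of 0 or near 0 for Hmgcs1, Eno1 and Snrpn (all 3 chosen after their values were seen), which many cells express at high levels, show that some genes were not counted in full, for a reason that was not tested. The tables held 24176 symbols in the same order and no summary rows. The reference at hand was of another build than mm9, so no coordinates are printed.

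From the counts, genes were kept with the edgeR function filterByExpr at its default minimum count of 10 and minimum total count of 15, library sizes were scaled with trimmed mean of M-values (TMM) factors, and DES was compared with ethanol with edgeR's quasi-likelihood test, with the group as the only term. Tests were two-sided, p-values were adjusted over all genes tested by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are TMM-normalized counts per 1000000 counts (CPM), computed here from the deposited counts, as mean ± SD with n = 3 per group. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

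Before the data were examined, 24 gene lists with 377 entries were fixed, together with the main test, most of the alternatives and the rule for naming genes. Bmp4 was the only gene held by 2 lists. Each list was compared with all other tested genes by limma's camera test on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 24 lists. It was tested again with a correlation estimated from the residuals. That version of camera has only 4 degrees of freedom here, in place of a number near that of the genes tested. Its p-values are thus larger even at a low correlation, so a failure does not show that correlation between genes made the list pass. Each list was also tested by fry, which asks whether its genes move on balance in one direction without comparing them with other genes. The number of members past the threshold is also given adjusted over the list alone.

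The rule named 5 receptors (Esrrb, Esrra, Esrrg, Esr1 and Esr2) and any member of the list of TS cell genes whatever the test showed, up to 4 members of each other list with the smallest adjusted p, and in each direction the 12 genes with the largest fold change among those past the threshold. These last had a mean of at least 100 counts in the higher group and no overlap between the groups, and genes named only by a model or clone number, microRNAs and small nucleolar RNAs were left out. Genes outside the rule are marked as named afterwards, which means that they were chosen after their values were seen.

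Total counts per library ranged from 37516981 to 40294598. At this depth the common biological coefficient of variation was 0.0441. Within each group, counts of the 11062 genes with a mean of at least 100 counts differed between every pair of libraries by more than sampling noise, with a chi-square per gene of 3.72 to 20.3. No library was thus a copy of another, which leaves open whether they came from independent cultures. The test was tried on simulated counts for the comparison of DES with ethanol, with the real means and library sizes, in which 13770 genes passed the filter. It recovered 73.5% of genes changed by 0.3 on the log2 scale, 81.6% at 0.5, 96% at 1 and 100% at 2, and 8 of its 180 calls were false. Only 48 to 50 genes of each size were changed, against 5464 genes past the threshold in the real data. Recovery and the share of false calls may therefore differ there. In separate simulated counts, in which only the genes of 1 planted list were changed, camera recovered that list and called 1 other. In simulated counts without any change, 3.33% of 480 lists had an unadjusted camera p under 0.05. All genes were drawn independently, so neither result tells how camera does with correlated genes. In the real data the estimated correlation of a list reached 0.444.

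Alternatives were DESeq2 size factors and upper-quartile factors in place of TMM, no count filter, a filter of 1 CPM in at least 3 libraries, DESeq2, limma-voom, a term for the replicate number, each library left out in turn, and a test against a 2-fold change (glmTreat). Chosen after seeing the data were the fit without the ribosomal RNA rows Rn45s and Mir6236, the fit with offsets for transcript GC content and length, and the fit with the share of Rn45s counts as a covariate. Transcript GC content and length came from GENCODE M21 transcripts matched by gene symbol, which gave a value to 99.4% of the tested genes. No library or count row was left out of the main comparison.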

Results

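Gene expression was measured by RNA-seq in the mouse trophoblast stem cell line F4. Trophoblast stem (TS) cells are self-renewing cells of the early trophoblast lineage and serve as a culture model of the extraembryonic ectoderm. The 6 libraries formed 2 groups of 3: cells grown for 2 days with 20 µM diethylstilbestrol (DES), a synthetic estrogen given in the labels as an inhibitor of the orphan nuclear receptor Esrrb, and cells grown with its vehicle, ethanol. Total counts were 40294598, 37553874 and 37741027 in DES replicates 1 to 3, and 37516981, 37883723 and 39831959 in ethanol replicates 1 to 3. Of 24176 gene symbols, 16900 to 17084 were detected per library and 13863 were tested. Rn45s, the precursor of the ribosomal RNAs, took 0.713% of the counts in ethanol replicate 1 and 0.151% to 0.235% in the other 5 libraries. The labels do not say whether the replicates were independent cultures, so the p-values measure only the spread between these samples, which may be technical.

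The title of the series concerns the role of Esrrb in the extraembryonic ectoderm and in primordial germ cell specification, and the comparison of DES with ethanol asks how TS cell gene expression differs when the receptor's inhibitor is present. In DES-treated cells, transcripts of Bmp4, which encodes the extraembryonic signal that induces primordial germ cells, fell 2.12-fold, from 96.9 ± 4.51 to 45.7 ± 2.18 CPM (SD, n = 3). The TS cell regulators Elf5, Eomes, Sox2 and Sox21 fell as well, while Esrrb itself and Cdx2 moved little. Of 13 measured genes of trophoblast giant cells, the polyploid invasive cells of the placenta, 11 rose and 1 fell, and of 17 epithelial genes, keratins among them, 11 rose and 1 fell. Neither list passed camera with an estimated correlation (adjusted p = 0.229 and 0.429), a test with only 4 degrees of freedom here. Several giant cell genes were scarce, and with a filter at 1 CPM 7 were called higher. Brachyury (T), a mesodermal T-box factor, fell 7.28-fold, from 6.13 ± 0.862 to 0.840 ± 0.138 CPM.

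With edgeR's quasi-likelihood test, 5464 of the 13863 tested genes (39.4%) passed the adjusted p threshold of 0.05, of which 2792 were higher and 2672 lower in DES. Which direction held more genes depended on the scaling, with 2666 higher and 2799 lower for upper-quartile factors, and 2932 higher and 3181 lower for GC and length offsets. Most changes were small. The median absolute log2 fold change of these genes was 0.305, and 4309 of them (78.9%) changed by less than 1.5-fold. A change of at least 2-fold was seen in 368 genes, 199 higher and 169 lower, and a test against a 2-fold change (glmTreat) passed 99. The 3 DES values all lay on one side of the 3 ethanol values in 48.2% of all tested genes, where chance gives 10%. Of the genes past the threshold that the naming rule covers, Rpl18, Rps2 and Trp53inp1 had overlapping groups. In a multidimensional scaling of the libraries, the first dimension held 61% of the variance and placed the DES libraries at -0.60 to -0.58 and the ethanol libraries at 0.58 to 0.61.

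**Figure D1:**
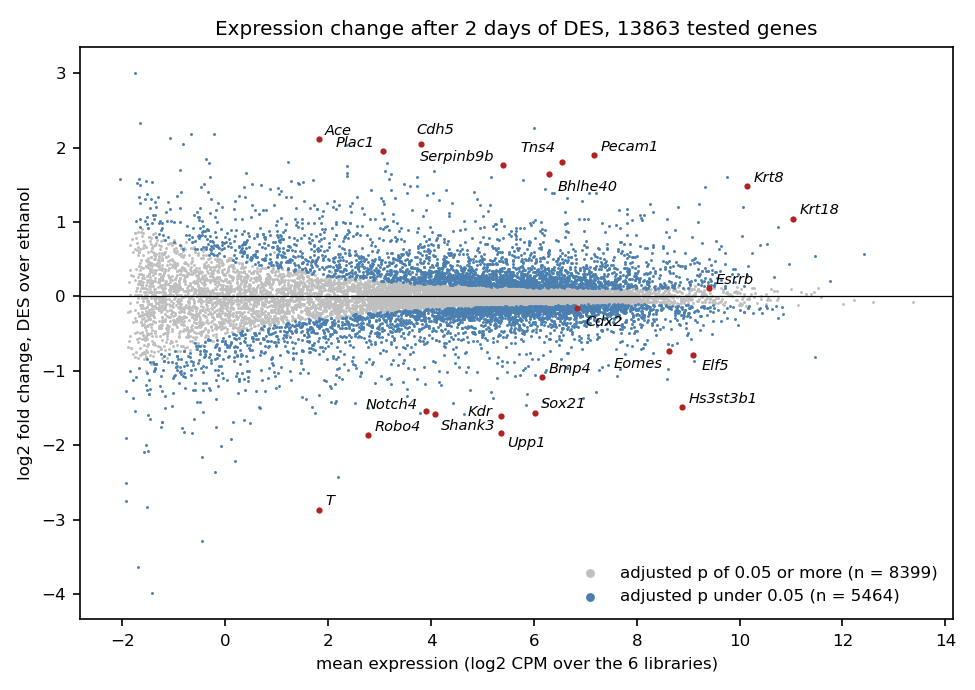
Log2 fold change of DES over ethanol (vertical axis) against mean expression in log2 CPM over the 6 libraries (horizontal axis), 1 point per tested gene, with 5464 genes of adjusted p under 0.05 in blue, the others in grey and some of the genes named in the text in red. Pecam1, Krt8 and Krt18 lie among the abundant genes above 1 on the vertical axis, T lies at -2.86, and Esrrb lies at 0.11.

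Esrrb transcripts were abundant in both groups and were not lower in DES. They stood at 654.4 ± 8.18 CPM in ethanol and 708 ± 18.4 CPM in DES (SD, n = 3), a log2 fold change of 0.11 (SE 0.0428, edgeR adjusted p = 0.0403). That call was lost with upper-quartile factors and on leaving out any 1 library except DES replicate 2, with adjusted p-values of 0.0112 to 0.123 over all alternatives with edgeR, DESeq2 and limma-voom, as in the ranges of other genes given over all alternatives. The related receptor gene Esrra stood at 34.3 ± 1.64 CPM in ethanol and 32.7 ± 2.63 CPM in DES (edgeR adjusted p = 0.391). Esrrg and the estrogen receptor gene Esr1 were near the detection limit, at 9 to 15 and 38 to 51 counts per library, and did not pass the threshold (edgeR adjusted p = 0.973 and 0.668). Esr2, the other classical estrogen receptor gene, had 0 to 3 counts per library and was not tested.

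The list of TS cell and extraembryonic ectoderm genes was lower in DES. Of 17 measured members, 10 fell, Esrrb alone was higher and 6 did not pass; adjusted over the list alone, 10 were lower and 2 higher. The largest decreases were those of Sox21 (log2 fold change -1.56, SE 0.0509), Zic3 (-1.09, SE 0.0631) and Bmp4 (-1.08, SE 0.0519). Elf5, which marks and maintains the TS cell state, fell from 696.3 ± 12 to 402.3 ± 7.77 CPM, and Eomes, a T-box factor needed for TS cell self-renewal, fell from 496.4 ± 8.53 to 298.5 ± 10.4 CPM (SD, n = 3). Sox2 (-0.76), Ets2 (-0.70), Lin28a (-0.40) and Satb1 (-0.39) also fell. Cdx2, the trophectoderm homeobox gene, fell by only 0.15 on the log2 scale (SE 0.0427, edgeR adjusted p = 0.00729). Not past the threshold were Tfap2c (0.10), Tead4 (0.07), the FGF receptor gene Fgfr2 (0.06), Klf5 (-0.01), Satb2 (-0.04) and Sall4 (-0.07), and Foxd3, at 3 to 12 counts per library, was not tested. Tfap2c passed as higher with a term for the replicate number (edgeR adjusted p = 0.0482, with 0.0482 to 0.19 over all alternatives). The list's median log2 fold change was -0.39 (camera adjusted p = 0.000395, and adjusted p = 0.229 with an estimated correlation).

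Among BMP ligands and the proprotein convertases that process such ligands, members went both ways. Bmp4, Pcsk6 (-0.71), Bmp7 (-0.64) and Bmp8a (-0.38, named afterwards) fell, Bmp8b (0.24) and Bmp2 (0.46, named afterwards) rose, and 3 of the 9 measured genes did not pass; the counts adjusted over the list alone were the same, 4 lower and 2 higher. Without DES replicate 1, ethanol replicate 1 or ethanol replicate 2, and with the Rn45s covariate or in DESeq2, 1 gene of this list was higher. Pcsk6 encodes the convertase PACE4 and fell from 152.7 ± 6.19 to 93.2 ± 2.26 CPM (SD, n = 3). Transcriptional targets of BMP and SMAD signalling were likewise mixed: Id2 (-0.98), Smad6 (-0.60), Id1 (-0.27) and Smad7 (-0.18) fell, Id3 (0.46) and Msx2 (0.22), both named afterwards, rose, and 3 of 9 did not pass, with 4 lower and 2 higher adjusted over the list alone. Of the response genes, 1 was higher in DESeq2 and without DES replicate 3, ethanol replicate 1 or ethanol replicate 2. As lists, neither differed from the other genes (camera adjusted p = 0.133 and 0.49).

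FGF4 sustains TS cells, and the response genes of FGF and ERK signalling changed in both directions. Of 17 measured, 8 fell, 5 rose and 4 did not pass, with 8 lower and 5 higher adjusted over the list alone. The ERK phosphatase gene Dusp6 fell by 0.92 on the log2 scale (SE 0.046), the Ets factor gene Etv4 by 0.61 and the feedback inhibitor gene Spry2 by 0.61. Dusp4, another ERK phosphatase gene, rose by 0.62 (SE 0.0478). The list as a whole did not pass (camera adjusted p = 0.202).

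Trophoblast giant cell genes were the list with the largest median change, 1.26 on the log2 scale. Of 13 measured members, 11 rose, Lifr (-0.61, named afterwards) fell and Ctsr (0.61, edgeR adjusted p = 0.105, named afterwards) did not pass; adjusted over the list alone, 12 were higher and 1 lower. Bhlhe40, a basic helix-loop-helix factor gene, rose from 37.9 ± 0.616 to 118.7 ± 1.22 CPM (SD, n = 3), and Serpinb9b (1.76) and Serpinb9e (1.48), of a granzyme inhibitor family, rose alike. The cyclin-dependent kinase inhibitor gene Cdkn1c rose from 97.2 ± 3.56 to 162.3 ± 2.54 CPM. The list passed (camera adjusted p = 2.63e-06, and adjusted p = 0.229 with an estimated correlation), but several members were scarce, and with a filter at 1 CPM 7 were called higher. The call of Lifr was lost without DES replicate 1 or ethanol replicate 1, where 0 genes of the list were lower. Prl4a1 and Ctsm had no counts, and Prl3b1 and Prl2c2 had at most 10 counts in any library (all 4 named afterwards).

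**Figure D2:**
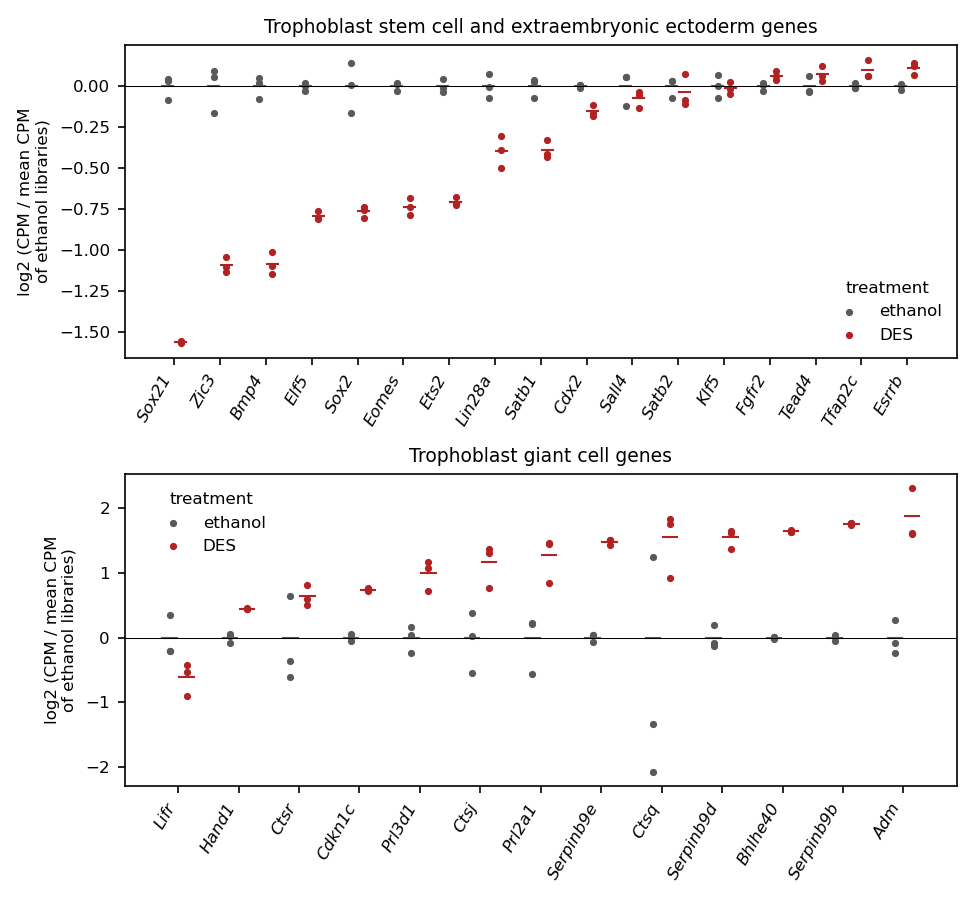
CPM of each library relative to the mean of the 3 ethanol libraries, on a log2 scale, for the 17 measured TS cell and extraembryonic ectoderm genes (upper panel) and the 13 measured trophoblast giant cell genes (lower panel), with 1 point per library, a short line at each group mean, and genes ordered by fold change. Sox21, Zic3 and Bmp4 lie lowest in DES while Fgfr2, Tead4, Tfap2c and Esrrb lie near the ethanol level, and 11 giant cell genes lie above it past the threshold.

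Genes of the other trophoblast derivatives did not differ as lists from the other tested genes. Of 9 measured spongiotrophoblast and glycogen cell genes, 3 rose, including Nrk (1.39) and Egfr (0.73) as well as Ascl2 (0.87, named afterwards), 2 fell, Pcdh12 (-0.53) and Gjb3 (-0.22), and 4 did not pass; adjusted over the list alone, 3 were higher and 3 lower. Camera gave this list an adjusted p of 0.856 in the upward direction although its median was -0.111, and by fry it passed as higher (adjusted p = 0.00494). The spongiotrophoblast marker gene Tpbpa (named afterwards) had 0 to 2 counts per library and was not tested. Of 9 syncytiotrophoblast and labyrinth genes, Tfeb (0.58) rose, the transporter genes Slc16a1 (-0.23) and Slc2a1 (-0.20) fell and 6 did not pass, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.619). Slc16a3 (-0.11, edgeR adjusted p = 0.104) was among the 6. It passed as lower with a replicate block (edgeR adjusted p = 0.0437) and with GC and length offsets (0.0157), with 0.0157 to 0.394 over all alternatives.

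Transcripts that TS cells share with pluripotent embryonic cells fell. Of 7 measured, 5 were lower, namely Utf1 (-0.59), Zfp42 (-0.52), Klf2 (-0.82), Dppa5a (-0.62) and Dppa4 (-0.22, named afterwards), and 2 did not pass; the count adjusted over the list alone was also 5. Utf1 fell from 351.7 ± 9.2 to 233.5 ± 7.24 CPM (SD, n = 3). The list's median was -0.521 (camera adjusted p = 0.00344, and adjusted p = 0.229 with an estimated correlation). Pou5f1, the core pluripotency gene (named afterwards), had 2 to 8 counts per library and was not tested.

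Epithelial genes rose, led by the keratins of simple epithelia. Members other than keratins moved less, with those past the threshold between -0.24 (Cdh1) and 0.45 (Esrp2), both named afterwards. Krt8 rose from 598.9 ± 36.3 to 1673 ± 45.2 CPM and Krt18, its filament partner, from 1371 ± 74.9 to 2832 ± 36.6 CPM (SD, n = 3), with Krt19 (1.28) and Krt7 (1.09) beside them. In all, 11 of 17 measured epithelial junction and keratin genes rose, 5 did not pass and 1 fell, Cdh1 (-0.24, named afterwards), which encodes E-cadherin; adjusted over the list alone, 11 were higher and 2 lower (camera adjusted p = 0.00123, and adjusted p = 0.429 with an estimated correlation). Without DES replicate 2 or ethanol replicate 1, 2 epithelial genes were lower. Of 9 mesenchymal genes, 5 rose and 4 did not pass, and the count adjusted over the list alone was also 5. Those that rose were Vim (0.74), Tagln (0.79), the fibronectin gene Fn1 (0.28), Itga5 (0.31) and Cdh2 (0.27, named afterwards). Camera passed the mesenchymal list (adjusted p = 0.0213, and adjusted p = 0.433 with an estimated correlation), but not without ethanol replicate 3 (adjusted p = 0.0589; 0.00646 to 0.0589 over the other settings with the preset correlation). By fry its adjusted p was 0.00351.

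Markers of cells that the cultures could also hold were scarce or mixed. Among 9 measured fibroblast genes, 3 rose, Col5a1 (0.78), Pdgfra (0.40) and Pdgfrb (0.44), Twist1 (-0.49) fell and 5 did not pass, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.111). The call of Pdgfrb was lost without DES replicate 1, DES replicate 3 or ethanol replicate 2, where edgeR adjusted p was 0.0512 to 0.0593; the range over all alternatives was 0.00244 to 0.0593. The major fibroblast collagen gene Col1a1 reached at most 0.954 CPM in any library, Col1a2 and Col3a1 had at most 3 counts, and Dcn and Lum had none (all 5 named afterwards). Among 9 primitive endoderm genes, 4 rose, the laminin genes Lamb1 (1.09) and Lama1 (0.44), Dab2 (0.82) and Foxa2 (0.32, named afterwards), Gata4 (-0.55) fell and 4 did not pass, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.42). Without DES replicate 3, 2 primitive endoderm genes were lower.

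Targets of the estrogen receptor that could be tested showed no common change, with DES being an estrogen. Pgr, Ltf, Igf1, C3 and Gper1 (all named afterwards) had at most 11 counts in any library and were not tested, which limits what the list can show. Of 6 measured, Wnt4 (1.30, at 13 to 55 counts per library, too few for the 1 CPM filter) rose, Rara (-0.26) fell and 4 did not pass, among them Greb1 (-0.34, edgeR adjusted p = 0.091) and Ramp3 (0.22, edgeR adjusted p = 0.207); the counts adjusted over the list alone were 1 higher and 1 lower (camera adjusted p = 0.856). Greb1 passed as lower without DES replicate 3 (edgeR adjusted p = 0.0302; 0.0302 to 0.36 over all alternatives) and Ramp3 as higher without ethanol replicate 3 (edgeR adjusted p = 0.0206; 0.0206 to 0.557). The NRF2 and AHR response, which meets oxidants and xenobiotics, had members past the threshold in both directions, with 3 of 16 genes higher, 3 lower and 10 not passing, likewise 3 and 3 adjusted over the list alone. Osgin1 fell by 1.33 on the log2 scale (SE 0.0732), while Tiparp (0.20) and Me1 (0.21) rose and Tkt (-0.13), Txnrd1 (0.11) and Nqo1 (-0.18) also passed, the last pair named afterwards. Tiparp lost its call without ethanol replicate 2, Me1 in DESeq2, with the Rn45s covariate and without DES replicate 3, ethanol replicate 2 or ethanol replicate 3, and Tkt without either DES replicate 2 or 3 or either ethanol replicate 2 or 3. Over all alternatives, the adjusted p-values from edgeR, DESeq2 and limma-voom reached 0.0701, 0.191 and 0.143 for these 3 genes. Of this list, 1 gene was higher without DES replicate 3 or ethanol replicate 2 and with the Rn45s covariate, 1 was lower without ethanol replicate 2 or 3, and 5 were lower with GC and length offsets. Camera gave this list an adjusted p of 0.856 in the downward direction, with a mean of -0.0985 and a median of 0.038, and by fry it passed as lower (adjusted p = 0.00885).

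Genes of the ATF4 integrated stress response, which includes serine synthesis and aminoacyl-tRNA synthetase genes, were lower in DES. Of 17 measured, 12 fell, Cebpb (0.28) and Ddit4 (0.20), both named afterwards, rose and 3 did not pass, with the same counts of 12 lower and 2 higher adjusted over the list alone. Without DES replicate 3 none of the list was higher, and 1 was without DES replicate 1, ethanol replicate 2 or ethanol replicate 3. Chac1, a glutathione-degrading enzyme gene, fell from 54.7 ± 1.28 to 28.7 ± 3.54 CPM (SD, n = 3), and Shmt2 (-0.42), Sars (-0.35) and Psat1 (-0.31) fell less. The median was -0.263 (camera adjusted p = 0.000395, and adjusted p = 0.478 with an estimated correlation). Endoplasmic reticulum chaperone genes rose: of 14, 11 were higher, Herpud1 (-0.17, named afterwards) was lower and 2 did not pass, again 11 and 1 adjusted over the list alone. The lower call was lost without DES replicate 1, DES replicate 2 or ethanol replicate 3, where 0 chaperone genes were lower. Pdia6 (0.46), Hspa5 (0.42), Hsp90b1 (0.37) and Calr (0.34) were among them (camera adjusted p = 0.00056, and adjusted p = 0.235 with an estimated correlation).

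Cholesterol synthesis and uptake genes rose as well. Of 22 measured, 15 were higher, Pmvk (-0.25, named afterwards) was lower and 6 did not pass, with 15 higher and 1 lower adjusted over the list alone. Without DES replicate 2, 0 were lower. The low density lipoprotein receptor gene Ldlr rose from 185.1 ± 5.66 to 280.7 ± 15.6 CPM (SD, n = 3), and the synthesis enzyme genes Fdps (0.71), Fdft1 (0.57) and Sqle (0.35) rose with it (camera adjusted p = 0.000196, and adjusted p = 0.519 with an estimated correlation).

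Proliferation genes were lower by small amounts. Of 18 DNA replication genes, 12 fell, Rrm2 (0.11, named afterwards) rose and 5 did not pass, with 12 lower and 1 higher adjusted over the list alone; the replicative helicase genes Mcm5 (-0.45), Mcm3 (-0.40), Mcm4 (-0.39) and Mcm2 (-0.38) led (camera adjusted p = 0.000196, and adjusted p = 0.429 with an estimated correlation). Of 17 mitosis genes, 10 fell and 7 did not pass, and 11 were lower adjusted over the list alone. Cenpf (-0.32), Kif11 (-0.28), Ccna2 (-0.24) and Ccnb2 (-0.20) were among them (camera adjusted p = 0.0043, and adjusted p = 0.429 with an estimated correlation), and 6 genes were lower without DES replicate 1, DES replicate 3 or ethanol replicate 2, while 1 was higher without DES replicate 2. In the DNA replication list, 0 genes were higher without any 1 library except ethanol replicate 2, where 2 were higher. Of 13 p53 targets, 5 rose and 8 did not pass, and the count adjusted over the list alone was also 5. These were the cell cycle inhibitor gene Cdkn1a (0.50), Mdm2 (0.39), Ccng1 (0.30), Trp53inp1 (0.22) and Pidd1 (0.22, named afterwards). The call of Trp53inp1 was lost in DESeq2 (adjusted p = 0.101) and without ethanol replicate 2 (edgeR adjusted p = 0.0531; 2.28e-05 to 0.101 over all alternatives). The p53 list did not pass (camera adjusted p = 0.0627), but passed without a count filter and without DES replicate 1, DES replicate 2, ethanol replicate 1 or ethanol replicate 3, with adjusted p-values of 0.0203 to 0.134 over these and the other settings with the preset correlation. Its adjusted p was 0.519 with an estimated correlation and 0.0164 by fry, and 1 p53 target was lower without DES replicate 3.

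Genes of energy metabolism moved little as lists, with 1 exception among single genes. Pdk1, which encodes a kinase that limits pyruvate entry into the citric acid cycle, fell from 178.2 ± 9.71 to 69.1 ± 4.85 CPM (SD, n = 3). Of the 15 measured glycolysis genes, Hk2 (0.32) and Tpi1 (0.23) rose, Pdk1, Gpi1 (-0.20) and Slc2a3 (-0.18, named afterwards) fell and 10 did not pass, with 2 higher and 3 lower adjusted over the list alone, and 6 were higher without DES replicate 2. Camera gave an adjusted p of 0.856 in the upward direction, with a mean of -0.0533. Of 24 mitochondrial respiration and citric acid cycle genes, 8 fell, among them Cox5b (-0.27), Cox5a (-0.25), Atp5a1 (-0.21) and Aco2 (-0.18), Ogdh (0.14, named afterwards) rose and 15 did not pass, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.13). In that list 0 genes were higher without DES replicate 1, 3 without DES replicate 2 or with a replicate block, and 2 without ethanol replicate 3. Cytosolic ribosomal protein genes served as a reference list. Of 20, Rpl18 (0.23) rose, Rpl27a (-0.16), Rpl23 (-0.13) and Rps2 (-0.14) fell and 16 did not pass, with 1 higher and 1 lower adjusted over the list alone. The call of Rpl18 was lost in DESeq2 and without DES replicate 1 or ethanol replicate 1, that of Rpl23 without any 1 of DES replicates 1 and 3 and ethanol replicates 1 and 3, and that of Rps2 without any 1 of DES replicates 1 and 2 and ethanol replicates 2 and 3. The highest adjusted p-values over all alternatives were 0.112 by DESeq2 for Rpl18, and 0.131 and 0.192 by edgeR for Rpl23 and Rps2. Of the list, 6 genes were higher without DES replicate 2, and 4 with a replicate block or without a count filter. In limma-voom, with the 1 CPM filter, without ethanol replicate 3, without ribosomal RNA rows and with GC and length offsets, 2 were higher. Without DES replicate 1 or ethanol replicate 3, 1 was lower. Camera gave an adjusted p of 0.856 in the downward direction, with a mean of 0.00676.

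Imprinted genes, many of which act in placental growth, changed in both directions. Of 18 measured, 6 rose, 4 fell and 8 did not pass, with 7 higher and 5 lower adjusted over the list alone; camera gave an adjusted p of 0.856 in the upward direction, with a mean of -0.0597. The growth factor gene Igf2 rose from 4370 ± 424 to 6519 ± 149 CPM (SD, n = 3) and Mest rose by 0.60 on the log2 scale (SE 0.0457). The noncoding RNA genes Meg3 (-0.70) and Rian (-0.64) fell, as did Mirg (-0.46) and Rtl1 (-0.91), both named afterwards, and all 4 belong to the Dlk1-Dio3 domain.

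**Figure D3:**
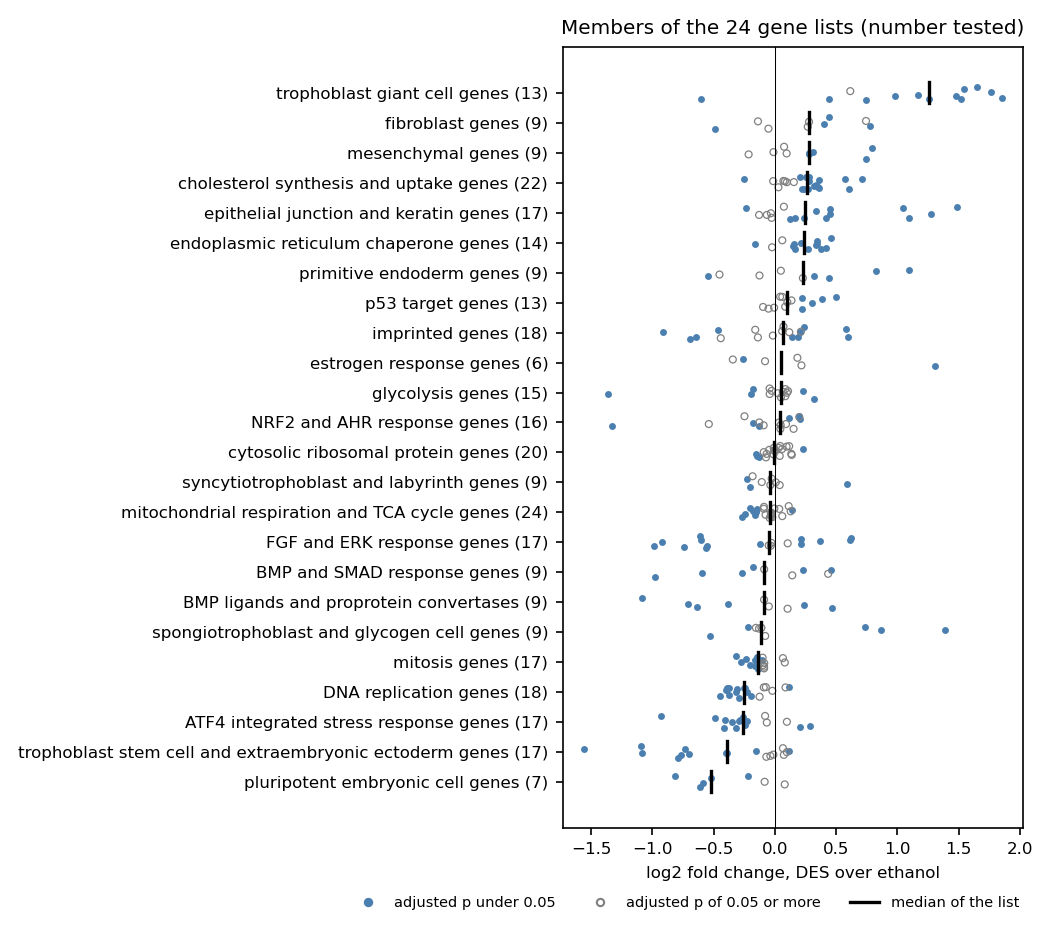
Log2 fold change of DES over ethanol (horizontal axis) of each tested member of the 24 gene lists, ordered by the list's median, with filled points for an adjusted p under 0.05, open points for the others and a bar at the median; the vertical spread within a list is only for display. The giant cell list lies highest with a median of 1.26 and the pluripotent list lowest with a median of -0.521.

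Across the 24 lists, 10 passed the camera threshold with the preset correlation, 5 higher and 5 lower. None passed camera with an estimated correlation, where the smallest adjusted p was 0.229 and 4 lists had an unadjusted p under 0.05. That test has only 4 degrees of freedom and thus larger p-values, so it does not tell whether correlation between genes made these lists pass. By fry, which does not compare a list with other genes, 18 lists passed. Those that camera did not pass were, as lower, the BMP ligand (adjusted p = 0.00228), BMP and SMAD response (0.0176), FGF and ERK response (0.00294) and NRF2 and AHR lists, and, as higher, the spongiotrophoblast, fibroblast (0.0244), primitive endoderm (0.00189) and p53 lists. Apart from the mesenchymal list, the camera adjusted p-values of the lists that passed stayed at or below 0.013 under the other settings with the preset correlation.

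The rule also named the genes with the largest fold changes among those with at least 100 counts. Ace, which encodes angiotensin-converting enzyme, rose 4.34-fold, Cdh5 (vascular endothelial cadherin) 4.12-fold, Lsp1 4.11-fold and Plac1, an X-linked placental gene, 3.88-fold. Pecam1, an adhesion molecule of endothelial and trophoblast cells, rose from 61.4 ± 9.83 to 228.5 ± 28.0 CPM (SD, n = 3). The others were Tns4 (1.81), Dlk2 (1.80), Mgll (1.79), Serpinb9b (1.76), Slco4a1 (1.76), Anxa1 (1.69) and Wnt7a (1.69). In the opposite direction, T led, followed by Robo4, an endothelial guidance receptor gene that fell 3.65-fold, Upp1, a uridine phosphorylase gene that fell 3.55-fold, and Kdr, a vascular endothelial growth factor receptor gene that fell from 61.5 ± 1.33 to 20.2 ± 0.658 CPM (SD, n = 3). Nr0b1, which encodes the orphan receptor Dax1, fell 2.95-fold. The rest were Spsb4 (-1.59), Shank3 (-1.57), Nptxr (-1.57), Sox21 (-1.56), Notch4 (-1.54), Zcchc12 (-1.50) and Golga7b (-1.49). For all of these, edgeR adjusted p-values lay between 1.31e-16 and 5.16e-06.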

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

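The alternatives without ribosomal RNA rows, with GC and length offsets and with an Rn45s covariate were chosen after the data were seen, the others before. Over the alternatives that gave a count with edgeR, DESeq2 or limma-voom at the same threshold, between 4420 and 6115 genes passed against 5464 in the main comparison. DESeq2 passed 4675 genes, with no adjusted p for 4736, limma-voom 5451, the fit without a count filter 5591 and the filter at 1 CPM 5238. Each of these fits shared 78.9% to 100% of the genes of the main comparison, and none of the shared genes had the opposite direction. Leaving out each library in turn gave 4420 genes (without DES replicate 1) to 5740 (without DES replicate 2), of which 2323 to 2988 were higher and 2097 to 2752 lower, 392 to 418 genes with a change of at least 2-fold, and 10 to 11 gene lists. The test against a 2-fold change, glmTreat, passed 99 genes in place of 368, since it asks that the change exceed 2-fold by more than its error. With an estimated correlation 0 gene lists passed camera at the adjusted threshold (4 had an unadjusted p under 0.05), and with fry 18 passed, against 10. Fry poses another question. Camera with an estimated correlation also has fewer degrees of freedom, 4 in place of a number near that of the genes tested, which raises p-values by itself. For the pluripotent list a higher correlation was not the cause, since its estimate was -0.104, under the preset 0.01. Its unadjusted camera p still rose from 0.00115 to 0.0286, which the fewer degrees of freedom account for. The other lists that passed had estimates of 0.0348 to 0.444, so both may have raised their p-values, and the 2 effects were not separated.

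The labels give both groups the replicate numbers 1 to 3. A replicate block in the fit passed 6115 genes, 371 of them changed at least 2-fold, and 10 gene lists. The labels name no pairing of cultures, so the main fit, fixed before the data were examined, had no term for the numbers. Same-numbered libraries deviated from their group means with correlations across genes of 0.0127, 0.124 and 0.149. As a hint from the data, each library correlated best with its own number over all genes, but over the 9459 genes with a mean log2 CPM above 3 the same-number correlations were -0.157, 0.234 and 0.433, and replicate 1 did not. Of 133 named genes, none that passed in the main comparison or in the alternative changed direction between them. Changes of direction in genes that passed in neither were not counted. Per alternative, 126 to 133 (131 of 131 with the 1 CPM filter) kept their side of the threshold. Depth limits the genes with few counts, such as Esrrg, Esr1, Wnt4 and the Prl and cathepsin genes.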

Other observations

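The gene groups of the first 2 paragraphs, the offsets for GC content and length, and the tests of the share of undifferentiated cells, of fibroblasts and of endothelial cells were chosen only after the results they concern were seen. Genes known from endothelial cells were among the most changed in both directions. Of 13 measured, 6 rose, namely Pecam1 (log2 fold change 1.90), Cdh5 (2.04), Thbd (1.56), Esam (0.84), Mmrn2 (0.50) and Plvap (0.28), 4 fell, namely Robo4 (-1.87), Kdr (-1.61), Notch4 (-1.54) and Eng (-0.24), and 3 did not pass. Genes of the Serpinb9 family of granzyme inhibitors rose in all 7 measured cases, with a median of 1.48, although these near-identical genes may share reads, which leaves the single values uncertain. Of 5 measured Rhox homeobox genes, an X-linked cluster, 4 rose, among them Rhox6 from 57.2 ± 1.70 to 143.5 ± 6.58 CPM (SD, n = 3) and Rhox9 (1.01).

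Enzyme genes that add 3-O-sulfate to heparan sulfate, the coreceptor of FGF4, changed in opposite directions. Hs3st3b1, abundant in ethanol, fell from 697.5 ± 7.85 to 249.4 ± 25.3 CPM (SD, n = 3) and Hs3st3a1 fell by 1.23 on the log2 scale, while Hs3st1 rose by 1.58. Of 12 measured Wnt ligand genes, 5 rose, namely Wnt7a (1.69), Wnt3 (1.37), Wnt4 (1.30), Wnt11 (0.92) and Wnt9a (0.74), Wnt6 (-1.26) and Wnt7b (-0.43) fell and 5 did not pass. In the imprinted Dlk1-Dio3 domain, the maternally expressed noncoding RNA genes Meg3, Rian and Mirg (-0.46) fell together with Rtl1 (-0.91), which is counted together with its antisense transcripts if the counting ignored strand, and Dlk1 (-0.44, edgeR adjusted p = 0.0731) did not pass.

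The first pattern weighed is the breadth of the change, 5464 genes. Bias by GC content or transcript length is argued against as the whole cause, since offsets for both left 6113 genes past the threshold, 5377 of them shared with the main comparison. The offsets differed between the groups by a median of 0.0151 and at most 0.268 on the log2 scale, against a median change of 0.305 in the genes past the threshold, so they corrected most genes little. Carry-over of ribosomal RNA in ethanol replicate 1 is argued against in the same way, since 4613 genes passed without that library. Of the 10 splits of the 6 libraries into 3 and 3, the real one alone (1 of 10) gave 5464 genes, and the highest of the other 9 gave 0 by edgeR (51 to 636 at an unadjusted p under 0.05). These 9 splits hold DES and ethanol libraries on both sides, so a difference between the groups widens the spread within each side and lowers their counts. They do not show what an unchanged comparison would give, and 10 splits are too few for a share under 0.05. A response of the cells to DES may account for the breadth, but a difference in handling between the groups that the labels do not record stays open.

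The second pattern is the fall of TS cell genes beside the rise of giant cell genes. A candidate explanation is a smaller share of undifferentiated cells in the DES cultures, and it stays open. The 17 measured members of the TS cell list differed from one another by far more than their errors (heterogeneity chi-square 1775, df 16), from -1.56 for Sox21 to 0.11 for Esrrb. Cells that lose these genes to unequal extents would give such a spread, and so would a change within stem cells, so the value does not separate the explanations. Fibroblasts from the conditioned medium are argued against as the source, since the highest level of Col1a1, Col1a2 or Col3a1 in any library was 0.954 CPM.

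The third pattern is the change of endothelial genes in both directions. Endothelial cells present in the DES cultures would bring all of their abundant transcripts, but 7 members of the group were too scarce to be tested. These were Tek, Tie1, Emcn, Vwf, Sox18, Icam2 and Cldn5, with a highest level of 0.24 CPM in any library, while Pecam1 reached 228.5 ± 28.0 CPM in DES (SD, n = 3). The test argues against endothelial cells as the source of the rise. Regulation of these genes within trophoblast cells may account for the pattern, as a hypothesis that no further test addressed.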
